A study of Mus musculus with 16 samples.

How the data were processed

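Messenger RNA from the ventricles of neonatal mice was sequenced in 16 samples, which form 4 groups of 4: wild-type (WT) and Chrna7 knockout (KO) mice, each after sham surgery or after surgical myocardial infarction (MI). Sham surgery is the same operation without tying off the coronary artery. Per the submitters' processing notes, the tools used were bcl2fastq 2.17, cutadapt 3.4, FastQC, HISAT2 2.2.1, HTSeq 0.13.5 and DESeq2, with genome build GRCm39; the notes give no order, strand setting or annotation release. The authors deposited unnormalised HTSeq counts, the number of reads assigned to each Ensembl gene in each sample. The table held 22468 genes, of which 21795 were protein-coding in the annotation available here, and 5 further lines of reads assigned to no gene. Reads in no annotated feature made up 23.7 to 28.3% of the reads counted in the table per library, and reads in more than 1 gene 1.56 to 2.08%. A symbol was available for 22362 genes, 52 genes shared a symbol with another, and 4354 genes had no count in any sample. The annotation available here was of an older build (GRCm38), so it served for gene names, chromosomes, distances between genes and transcript length and GC content, and no coordinates are given. Because the strand setting is not stated, counts of genes that overlap on opposite strands may include reads of the other gene.

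Groups were taken from the labels, which state the genotype and the surgery of each sample but not the litter, sex, age at harvest or whether each sample is a separate animal. The p-values therefore measure only the spread between these samples. The counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, the filterByExpr filter on the 4 groups (13412 genes tested), and a robust quasi-likelihood fit of all 16 samples with a mean per group and 12 residual degrees of freedom. Contrasts were tested on both sides, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 5 comparisons were infarction against sham in each genotype, knockout against wild type after each surgery, and the interaction, which is the response to infarction in knockout minus that in wild type. Fold changes are given on the log2 scale with the standard error implied by the F statistic. Levels are in the standard unit CPM of the edgeR cpm function, with TMM-scaled library totals, as mean ± SD.

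A set of 47 gene lists (cell types, pathways and markers of sample quality; 876 of 886 listed symbols found) was written before the data were examined, as were the comparisons, the tests, the alternatives named first below and the rule for named genes. Where a listed symbol belonged to more than 1 gene, each was counted. The 46 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists. Each was also tested with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare the list with other genes. The counts of genes called in a list are given over all genes tested and adjusted over the list alone. The rule named, for each comparison, up to 10 genes that rose and 10 that fell with the largest fold change among called genes with a mean of at least 2 CPM in 1 of the groups compared, no overlap between the replicates of the groups compared (not required for the interaction) and a symbol other than a predicted gene model. It further named the 2 to 4 members of each described list with the smallest p, and Chrna7, Tnf, Il1b, Il6, Il10, Nppa, Nppb, Mki67, Ccnb1, Aurkb, Anln and the Y-linked genes, and genes within 20 Mb of Chrna7 that were called between genotypes after both surgeries, of which there were none. Other genes are marked where named.

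The alternatives were the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with sample quality weights, RLE and upper quartile scaling, no filter and a filter at a mean of 50 counts, leaving out haemoglobin and mitochondrially encoded genes, a block for the replicate number, an index of Y-linked expression as a covariate, a fit of the 8 samples compared alone, and leaving out each library in turn. The index was planned from Xist and the Y-linked genes, but Xist was absent from the table. Further alternatives, chosen after seeing the data, left out 3 libraries with almost no Y-linked reads, left out the 3 libraries that stood apart on the fourth principal component, added an atrial index (mean log2 CPM of Myl7, Myl4 and Sln) as a covariate, thinned all libraries to the smallest total, and corrected each library for trends with transcript length and GC content. Principal components were computed on log2 CPM with a prior count of 2. Comparisons of a single value between groups used two-sided exact permutation tests, whose smallest possible p with 4 against 4 samples is 0.029.

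The gene counts per library ranged from 10711442 to 17223580. A floor of 3 counts corresponds to 0.179 to 0.29 CPM, depending on the library; it covers counting error only, since PCR copies are not independent molecules. Levels are given where a group lies at or below this floor. Where a fitted log2 change is given beside them, it rests on few counts in that group. The fit was tested on simulated data in which genes with a mean above 1 CPM were changed by known amounts. For the response to infarction in wild type (13294 genes), 42.4% of genes changed by 0.5 on the log2 scale, 91% of those changed by 1 and 92.5% of those changed by 1.5 were recovered. The shares were 54.5, 89.6 and 98.5% for the response in knockout (13316 genes), 47, 86.6 and 95.5% for knockout against wild type after infarction (13311 genes), 40.9, 95.5 and 98.5% for the same contrast after sham (13309 genes), and 16.7, 68.7 and 92.5% for the interaction (13297 genes). False calls made up 4.7 to 6.3% of the calls, depending on the comparison. The simulated counts were drawn independently for each gene, with the same spread in all groups and no library-wide deviation. The deposited libraries do deviate. KO MI replicate 4 differed from the others of its group by a median of 0.259 on the log2 scale (0.095 to 0.2 for the other libraries). These rates may therefore not hold for the deposited data.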

Results

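Gene expression was measured in the ventricles of neonatal mice, a stage at which the mouse heart can still replace lost muscle. The mice were wild type or lacked Chrna7, the gene of the alpha 7 nicotinic acetylcholine receptor, through which acetylcholine dampens cytokine release by macrophages. Each genotype had 4 samples after sham surgery and 4 after myocardial infarction. The gene counts per sample ranged from 10711442 to 13504923 in WT sham, 10871418 to 17223580 in WT MI, 12449879 to 15501352 in KO sham and 13857909 to 14683416 in KO MI. Haemoglobin transcripts, which come from red blood cells, stood at 3790 ± 856 CPM (SD, n = 4) in WT sham, 1816 ± 187 in WT MI, 1096 ± 177 in KO sham and 1320 ± 310 in KO MI. Mitochondrially encoded genes took 10.6 ± 1.91%, 11.3 ± 1.09%, 12.4 ± 0.497% and 12 ± 3.58% of the counts in the same order. The Y-linked genes were close to absent in WT sham replicate 1 (1.73 CPM), KO sham replicate 2 (2.13 CPM) and KO MI replicate 1 (2.74 CPM), and the labels do not state the sex.

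The KO sham samples stood apart from the other groups on the first principal component, which held 25.5% of the variance. Their scores lay between 27.9 and 31.6, while no other sample scored above 1.

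**Figure D1:**
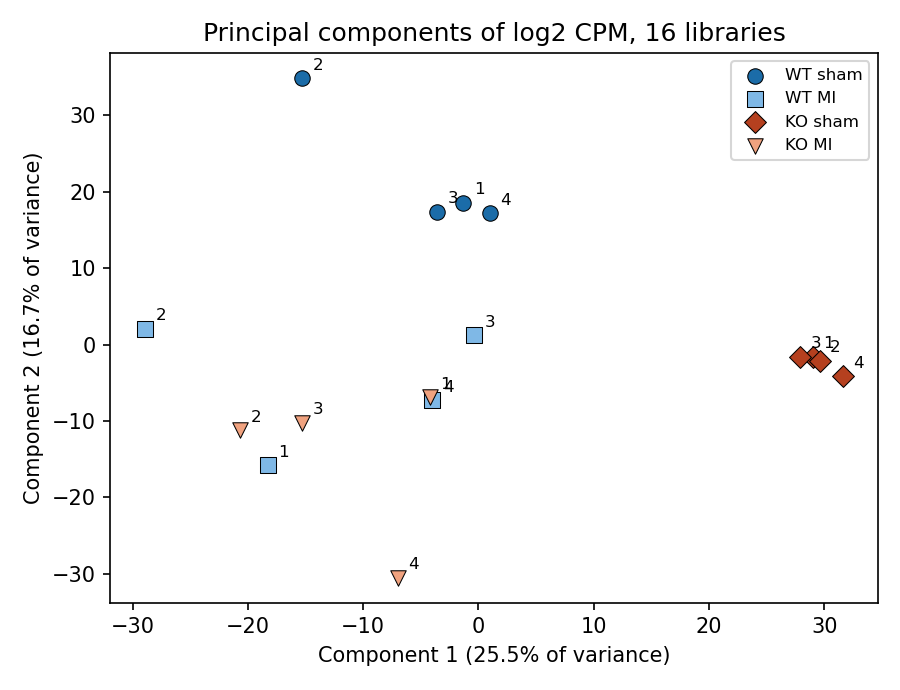
Scores of the 16 samples on principal component 1 (25.5% of the variance) and component 2 (16.7%), computed from log2 CPM, where each point is a sample, coloured by group, with its replicate number. The KO sham samples score 27.9 to 31.6 on component 1 and no other sample scores above 1.

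Chrna7 (ENSMUSG00000030525, chromosome 7) was at or near the detection floor in every sample, with 0 to 4 reads. After sham surgery its level was 0.0568 ± 0.071 CPM in knockout and 0.0873 ± 0.102 CPM in wild type (SD, n = 4; two-sided exact permutation p = 0.657). After infarction it was 0.187 ± 0.0601 CPM in knockout and 0.064 ± 0.0797 CPM in wild type (exact permutation p = 0.0857). Counts of the whole gene cannot be assigned to the deleted part, and wild type had 7 reads in 8 samples, so these values check neither the deletion nor the labels. Of the 209 tested genes within 20 Mb of Chrna7, 37 were called between genotypes after sham (17.7%), against 15.3% of all others (odds ratio 1.19, Fisher exact p = 0.334).

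Infarction against sham in wild type asks how the normal neonatal heart responds to injury. C3ar1, a complement receptor of myeloid cells, rose 2.78 times (log2 1.47 ± 0.24, SE, n = 4 per group, adjusted p = 0.00277), and Pirb, an inhibitory receptor of myeloid cells, rose 4 times (adjusted p = 0.00629). Ccn5, a secreted growth regulator, rose 4.59 times (adjusted p = 0.00309), and C1qtnf3, a secreted C1q-like protein, rose 5.97 times (2.58 ± 0.49, adjusted p = 0.00879). In all, 302 genes changed, 177 rising and 125 falling. The share that rose was 58.6%, and 47.4% without WT sham replicate 2.

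The 17 pan-leukocyte genes moved up together, with 5 rising over all genes and 15 adjusted over the list alone (median log2 0.84, camera adjusted p = 3.08e-15, adjusted p = 0.0885 with an estimated correlation). Of 21 inflammatory monocyte and macrophage genes 2 rose, and 14 did when adjusted over the list alone (median 1.04, adjusted p = 0.0498 with an estimated correlation). Of 13 complement genes 4 rose, and 12 when adjusted over the list alone (median 0.61, adjusted p = 0.0483 with an estimated correlation); among them C1qa, which starts the classical cascade, rose 1.66 times. Of 22 resident macrophage genes 6 rose, and 10 rose and 1 fell when adjusted over the list alone (median 0.42, adjusted p = 0.0972 with an estimated correlation); the Fc receptor-like gene Fcrls rose 1.84 times. Of 15 neutrophil genes 2 rose, and 9 when adjusted over the list alone (median 1.86, adjusted p = 0.21 with an estimated correlation). Cd14, the co-receptor for bacterial lipopolysaccharide, rose 1.94 times, a call that ended without WT MI replicate 1 (log2 0.69). Osteopontin (Spp1) stood at 0.858 ± 0.501 CPM after sham and 21.3 ± 13.7 CPM after infarction, a call that ended in 5 of 8 leave-one-out fits (log2 4.30 to 5.05). Il1b, an inflammatory cytokine, rose 6.52 times, and its call ended in 5 of these fits (log2 1.54 to 2.99). The scavenger receptor Marco went from 0.245 CPM, at the floor, to 2.72 CPM (fitted log2 3.45, and 2.68 without WT MI replicate 1), a call that ended in 6. Tnf, Il6 and Il10 were too low to be tested.

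In muscle and matrix, Xirp2, which binds actin at the cell junctions of heart muscle, rose 2.15 times (log2 1.10 ± 0.20, adjusted p = 0.00803), and skeletal actin (Acta1) rose 1.88 times (0.91 ± 0.20, adjusted p = 0.0234). The fetal troponin Tnni1 fell by 0.73 on the log2 scale (SE 0.12, adjusted p = 0.00372). Cilp, a matrix protein of fibroblasts, rose 3.04 times and Cthrc1, a marker of activated fibroblasts, 1.67 times. The transcription factor Nr4a3 fell from 11.2 ± 3.64 to 1.65 ± 0.753 CPM, and the growth regulators Dlk1 and Igf2 fell by 1.21 and 0.63 on the log2 scale. Ppargc1a, a regulator of mitochondrial genes, fell by 1.07, a call that ended without WT MI replicate 1 (log2 -1.03), and the hypoxia-induced Ankrd37 rose 2.23 times. The haemoglobin gene Hba-a1 was 2.27 times lower after infarction, with 6 of 13 erythroid genes falling over all genes and 6 adjusted over the list alone (median -0.24, adjusted p = 0.0483 with an estimated correlation). Of 14 epicardium and mesothelium genes 1 fell, and 6 fell and 1 rose adjusted over the list alone (median -0.82, adjusted p = 0.327 with an estimated correlation). The 9 lymphatic endothelium genes, of the vessels that drain tissue fluid, were all negative, with none called over all genes and 2 falling adjusted over the list alone (median -0.25, camera adjusted p = 0.00153, adjusted p = 0.0483 with an estimated correlation). The 30 oxidative phosphorylation genes moved down by a median of -0.13 with no single gene called (adjusted p = 0.427 with an estimated correlation). Nppa (log2 0.15 ± 0.58), Nppb (0.57 ± 0.27), Mki67 (0.09 ± 0.13), Ccnb1 (0.18 ± 0.16), Aurkb (-0.05 ± 0.17) and Anln (0.07 ± 0.14) did not pass.

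The number of genes fell to 86 without WT MI replicate 1, 134 without WT sham replicate 3, 162 without WT sham replicate 4 and 178 without WT sham replicate 1. Of the 46 lists 25 were called, 17 up and 8 down, and 4 with an estimated correlation, namely monocyte and macrophage, complement, erythroid and lymphatic endothelium.

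Infarction against sham in knockout asks the same of hearts without the receptor. The KO sham samples, which stood apart on the first principal component, are the reference here. They also enter knockout against wild type after sham and the interaction, so these comparisons are not independent. Genes low in KO sham for any reason, such as an unstated litter or age, would appear here as rising with infarction. Mmp12, a macrophage elastase, went from 0.358 ± 0.138 to 7.34 ± 2.1 CPM (log2 4.30 ± 0.45, SE, n = 4 per group, adjusted p = 3.4e-05), and C3, the central complement protein, rose 21 times from 8.04 ± 0.905 to 169 ± 127 CPM. Spp1 rose 54.7 times (5.77 ± 0.85, adjusted p = 0.00129, and 5.10 without KO MI replicate 2). In all, 2220 genes changed, 1145 rising and 1075 falling. The share that rose, 51.6%, was 60.6% with upper quartile scaling (1368 rising, 889 falling) and 41.8% with the length and GC correction (879 rising, 1226 falling), and 46.7% without KO MI replicate 4, so neither direction held the majority throughout.

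Of 21 inflammatory monocyte and macrophage genes 15 rose, and 16 rose and 1 fell adjusted over the list alone (median log2 1.66, adjusted p = 0.0871 with an estimated correlation). Among them Trem2, a lipid receptor of macrophages, rose 3.52 times, galectin 3 (Lgals3) 4.81 times and Gpnmb 13.2 times (log2 3.72, and 2.92 without KO MI replicate 2). Arginase 1 (Arg1) rose 132 times to 51.7 ± 67.8 CPM, with 152 CPM in KO MI replicate 3 and 4.32 to 26.6 in the other 3 (log2 7.04, and 5.53 without KO MI replicate 3). Of 13 complement genes 10 rose over all genes and adjusted over the list alone (adjusted p = 0.0871 with an estimated correlation), C1qb 2.18 times and properdin (Cfp) 2.28 times. Of 17 pan-leukocyte genes 10 rose, and 14 adjusted over the list alone (median 0.77, adjusted p = 0.159 with an estimated correlation), the integrin Itgb2 2.89 times. Of 15 neutrophil genes 10 rose, and 12 adjusted over the list alone (median 1.67, adjusted p = 0.159 with an estimated correlation), the granule protein Ngp 5.56 times. Of 19 cytokine and chemokine genes 9 rose and 2 fell, and 10 rose and 2 fell adjusted over the list alone (median 1.34, and -0.35 with a filter at a mean of 50 counts, adjusted p = 0.159 with an estimated correlation). The monocyte attractants Ccl2 and Ccl9 rose 2.53 and 4.35 times. Il1b rose 4.12 times, a call that ended in 7 of 8 leave-one-out fits. Marco went from 0.147 to 5.85 CPM, the collagen Col6a5 from 0.225 to 20 ± 23.4 CPM and Dmkn from 0.088 to 2.18 CPM, each at or below the floor after sham. Col6a5 stood at 54.3 CPM in KO MI replicate 3 and at 1.67 to 12.7 CPM in the other 3, and its fitted log2 change of 6.45 was 5.22 without KO MI replicate 3.

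Of 14 epicardium and mesothelium genes 11 rose, over all genes and adjusted over the list alone (median 1.72, camera adjusted p = 1.44e-08, adjusted p = 0.157 with an estimated correlation). The keratins Krt8 and Krt18 rose 3.61 and 2.6 times and uroplakin Upk1b 7.98 times. Of 23 genes of the G1/S phase, when DNA is copied, 18 rose, and 20 adjusted over the list alone (median 0.51, adjusted p = 0.159 with an estimated correlation). Among them the helicase subunit Mcm3 rose 1.55 times and cyclin E1 (Ccne1) 1.72 times. Of 25 G2/M genes 10 rose, and 18 adjusted over the list alone (median 0.4, adjusted p = 0.349 with an estimated correlation), Top2a 1.46 times. Mki67 (0.19 ± 0.13), Ccnb1 (0.45 ± 0.16), Aurkb (0.40 ± 0.17) and Anln (0.27 ± 0.14) did not pass.

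In muscle, the calcium pump Atp2a2 was 1.61 times lower (log2 -0.68 ± 0.11, adjusted p = 0.000517), while Tnni1 rose 1.79 times (0.84 ± 0.12, adjusted p = 0.000342) and Acta1 2.52 times (1.33 ± 0.20, adjusted p = 0.000703). Of 10 skeletal muscle genes, which include Acta1, 2 rose, and 3 adjusted over the list alone (median 0.37, camera adjusted p = 0.00155, adjusted p = 0.157 with an estimated correlation), the developmental myosin Myh8 from 1.08 ± 0.192 to 4.3 ± 1.69 CPM. Of 25 cardiomyocyte genes 6 fell, and 8 adjusted over the list alone (adjusted p = 0.258 with an estimated correlation). Titin (Ttn) fell by 0.50, and by 0.11, without passing, after a correction for transcript length and GC content. Nppa, the atrial natriuretic peptide, rose 5.68 times, a call that ended without KO sham replicates 2 and 4, each left out alone; its log2 change was 2.50 ± 0.61 and 1.39 with the atrial index as a covariate. That index was 5.22 ± 0.52 in KO sham and 6.29 ± 0.76 in KO MI. The glucose-sparing kinase Pdk4 fell by 1.12 and the fatty acid oxidation enzyme Cpt1a by 0.48. Of 24 fatty acid oxidation genes 6 fell, and 8 adjusted over the list alone (adjusted p = 0.159 with an estimated correlation). Of 28 glycolysis and hypoxia genes 14 rose, and 17 rose and 1 fell adjusted over the list alone (adjusted p = 0.157 with an estimated correlation), the lactate carrier Slc16a3 3.47 times. Insulin-degrading enzyme (Ide) went from 223 ± 14 to 87 ± 20.3 CPM. Zbtb16, a glucocorticoid-induced transcription factor, was 4.09 times lower (log2 -2.03, and -2.84 without KO MI replicate 4), and the kinase Mylk4 2.77 times. Of 22 immediate early and handling stress genes 11 rose, and 14 adjusted over the list alone (adjusted p = 0.159 with an estimated correlation), Fos 6.08 times. Of 30 ribosomal protein genes 22 rose, and 29 adjusted over the list alone (median 0.34, adjusted p = 0.274 with an estimated correlation); for Rpl6 the log2 change was 0.36 ± 0.08, and 0.12, without passing, after the length and GC correction.

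The number of genes was 1388 without KO sham replicate 1, 1380 without KO sham replicate 2, 1305 without KO sham replicate 4, 1230 without KO MI replicate 2 and 1443 without KO MI replicate 3. Of the 46 lists 26 were called, 21 up and 5 down, and none with an estimated correlation.

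Across the 13412 genes tested, the log2 responses in the 2 genotypes had a Pearson correlation of 0.331; genes are not independent replicates. Called genes shared by both responses numbered 63 that rose, 29 that fell and 22 that went opposite ways. Independent lists would share 15.1 rising and 10 falling genes. No such number was computed for opposite directions, so the 22 do not by themselves show responses turned by the genotype.

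**Figure D2:**
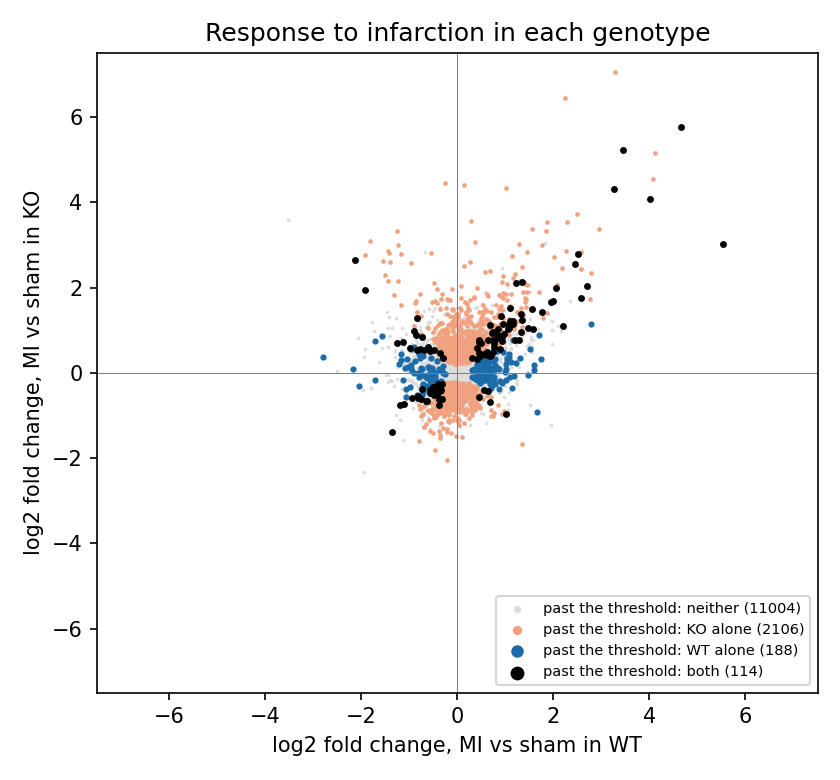
Log2 fold change of each tested gene after infarction against sham, in wild type (horizontal axis) and in knockout (vertical axis), with a point per gene, coloured by whether it passed an adjusted p of 0.05 in both genotypes (114 genes), in wild type alone (188), in knockout alone (2106) or in neither. Passing in 1 genotype alone does not show that the responses differ, which the interaction tests.

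Knockout against wild type after infarction asks whether injured hearts differ without the receptor. The mitochondrial gene mt-Nd3 (ENSMUSG00000064360), a subunit of respiratory complex I, was 5.68 times higher in knockout, at 38.2 ± 5.44 against 6.75 ± 1.23 CPM (log2 2.51 ± 0.17, SE, n = 4 per group, adjusted p = 3.14e-08). Counts differed widely among the mitochondrially encoded genes. In KO MI and WT MI, mt-Nd1 stood at 19200 ± 8840 and 15900 ± 1850 CPM, and mt-Nd4l at 8.63 ± 6.92 and 5.13 ± 1.25 CPM. Mylk3 (ENSMUSG00000031698, chromosome 8), the kinase of the cardiac myosin light chain, was 1.46 times lower, at 392 ± 25.9 against 571 ± 52 CPM (-0.54 ± 0.09, adjusted p = 0.0251). Its call ended without WT MI replicate 1, WT MI replicate 3, KO MI replicate 2 or KO MI replicate 3 (log2 -0.59 to -0.47 over all leave-one-out fits). Mylk3 was also called lower in knockout after sham (log2 -0.4 ± 0.09, adjusted p = 0.00416), so its difference was not confined to injured hearts. No other gene passed after infarction. Of the 13412 genes tested, 638 had an unadjusted p under 0.05 in edgeR, no more than chance alone would give, and DESeq2 called 10. Acta1 (-1.01 ± 0.20, adjusted p = 0.166), Il1b (-1.14 ± 0.50), Nppa (0.02 ± 0.58), Nppb (-0.20 ± 0.27), Mki67 (-0.06 ± 0.13), Ccnb1 (-0.08 ± 0.16), Aurkb (-0.03 ± 0.17) and Anln (-0.11 ± 0.14) did not pass.

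Macrophage lists were called higher in knockout with the preset correlation, none of them with an estimated correlation, and no gene in them passed over all genes. The lung epithelium list, a marker of another tissue, was called higher too, with 10 of 10 genes positive and none passing, over all genes or adjusted over the list alone (median 0.54, camera adjusted p = 0.0341, adjusted p = 0.575 with an estimated correlation). Its call ended without WT MI replicate 2 (0.11), WT MI replicate 4 (0.35) or KO MI replicate 4 (-0.04), and its median was -0.39 without the 3 libraries apart on the fourth principal component. Of 21 inflammatory monocyte and macrophage genes 6 rose adjusted over the list alone (median 0.56, camera adjusted p = 1.27e-07, adjusted p = 0.202 with an estimated correlation). Of 13 complement genes 4 rose adjusted over the list alone (median 0.35, adjusted p = 0.202 with an estimated correlation), and of 22 resident macrophage genes 1 did (median 0.23, adjusted p = 0.202 with an estimated correlation). Of 17 pan-leukocyte genes 1 rose adjusted over the list alone (median 0.35, adjusted p = 0.266 with an estimated correlation), and of 11 dendritic cell and antigen presentation genes 1 (median 0.48, adjusted p = 0.202 with an estimated correlation). The erythroid list was lower (median -0.4, adjusted p = 0.157 with an estimated correlation), as were the cardiomyocyte list (-0.13, adjusted p = 0.209 with an estimated correlation) and the matrix list (-0.13, adjusted p = 0.339 with an estimated correlation), whose call ended without KO MI replicate 4 (-0.07). The 30 ribosomal protein genes were higher by a median of 0.16 (adjusted p = 0.42 with an estimated correlation), and the 13 mitochondrially encoded genes by 0.09 (adjusted p = 0.44 with an estimated correlation), a call that ended without WT MI replicate 1 (0.03) and KO MI replicate 4 (-0.17). The number of genes was 1 without WT MI replicate 1, KO MI replicate 2 or KO MI replicate 3, and 4 without WT MI replicate 2 or KO MI replicate 4. Of the 46 lists 18 were called, none of them with an estimated correlation.

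Knockout against wild type after sham asks whether the receptor matters without injury. The haemoglobin gene Hbb-bt was 3.92 times lower (log2 -1.97 ± 0.16, SE, n = 4 per group, adjusted p = 4.29e-07), and Hba-a1 went from 1460 ± 370 CPM in wild type to 384 ± 72.6 CPM. Tnni1 was 2.63 times lower, at 412 ± 39.2 against 1080 ± 150 CPM (-1.39 ± 0.13, adjusted p = 1.06e-06). The transcription factor Nr4a1 was 14.3 times lower, at 14 ± 1.2 against 200 ± 45.9 CPM. In all, 2057 genes differed, 1019 higher and 1038 lower in knockout. The share that was higher, 49.5%, was 56.6% without haemoglobin and mitochondrially encoded genes, 46.2% without the libraries low in Y-linked reads and 41.8% without WT sham replicate 2.

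Of 13 erythroid genes 10 were lower, over all genes and adjusted over the list alone (median -1.64, adjusted p = 0.00461 with an estimated correlation); Alas2, which starts haem synthesis in red cells, was 2.78 times lower. Of 14 epicardium and mesothelium genes 12 were lower, over all genes and adjusted over the list alone (median -1.84, adjusted p = 0.105 with an estimated correlation). Mesothelin (Msln) was 11.1 times lower, Upk3b 16.4 times and Upk1b 8.36 times. Muc16 stood at 3.33 CPM in wild type and 0.201 CPM in knockout, near the floor. C3 was 8.48 times lower. Of 22 immediate early and handling stress genes 11 were lower, and 15 were lower and 1 higher adjusted over the list alone (median -0.68, adjusted p = 0.105 with an estimated correlation), Fos 10.7 times and Atf3 4.61 times. This list was also written to mark handling of the samples, and a difference in handling was not tested.

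Among 18 genes of the fetal and stress programme of heart muscle 9 were lower and 1 higher, and 10 lower and 1 higher adjusted over the list alone (median -0.39, adjusted p = 0.105 with an estimated correlation); Acta1 was 2.71 times lower. Of 10 skeletal muscle genes, which also include Acta1, 5 were lower, over all genes and adjusted over the list alone (median -0.32, camera adjusted p = 0.00105, adjusted p = 0.113 with an estimated correlation); Myh8 stood at 1.08 ± 0.192 CPM in knockout and 7.22 ± 3.02 CPM in wild type. Of 11 atrial genes 7 were lower, and 8 adjusted over the list alone (median -1.02, adjusted p = 0.36 with an estimated correlation). The atrial myosin light chains Myl7 and Myl4 were 4.87 and 4.73 times lower, and the atrial index was 5.22 ± 0.52 in KO sham and 7.37 ± 0.88 in WT sham. Nppa was 5.04 times lower (log2 -2.33 ± 0.61, and -0.26 with the atrial index as a covariate), a call that ended without WT sham replicate 1 or KO sham replicate 1, 2 or 4. Plin1, the fat droplet protein of adipocytes, stood at 0.0536 ± 0.0709 CPM in knockout, below the floor, and 2.18 ± 2.59 CPM in wild type. Of 28 glycolysis and hypoxia genes 15 were lower and 1 higher, and 17 lower and 1 higher adjusted over the list alone (adjusted p = 0.206 with an estimated correlation), Slc16a3 2.33 times. Of 24 fatty acid oxidation genes 7 were higher, and 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.454 with an estimated correlation), Pdk4 1.81 times. Of 23 G1/S genes 8 were lower, and 13 adjusted over the list alone (median -0.34, adjusted p = 0.454 with an estimated correlation), and of 25 G2/M genes 6, and 13 adjusted over the list alone (median -0.33, adjusted p = 0.492 with an estimated correlation). Mki67 (-0.16 ± 0.13) and Aurkb (-0.47 ± 0.17) did not pass.

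Genes higher in knockout included mt-Nd3, 5.53 times, and Zbtb16, 7.14 times (log2 2.84 ± 0.46, adjusted p = 0.00119). The death ligand Tnfsf10 was 3.76 times higher and the glycosyltransferase Galnt15 3.37 times. Of 18 quiescent fibroblast genes 6 were higher and 1 lower, and 9 higher and 2 lower adjusted over the list alone (median 0.29, adjusted p = 0.113 with an estimated correlation), the ferritin receptor Scara5 2.39 times. Of 22 resident macrophage genes 5 were higher and 1 lower, and 8 higher and 2 lower adjusted over the list alone (median 0.25, adjusted p = 0.492 with an estimated correlation), a call that ended without WT sham replicate 3 (0.22) or WT sham replicate 4 (0.25). Il1b (-0.48 ± 0.80) did not pass. The number of genes was 1351 without WT sham replicate 3, 1329 without KO sham replicate 1, 1322 without KO sham replicate 2 and 1298 without KO sham replicate 4, and 928 with the atrial index as a covariate. Of the 46 lists 19 were called, 7 up and 12 down, and 1 with an estimated correlation.

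**Figure D3:**
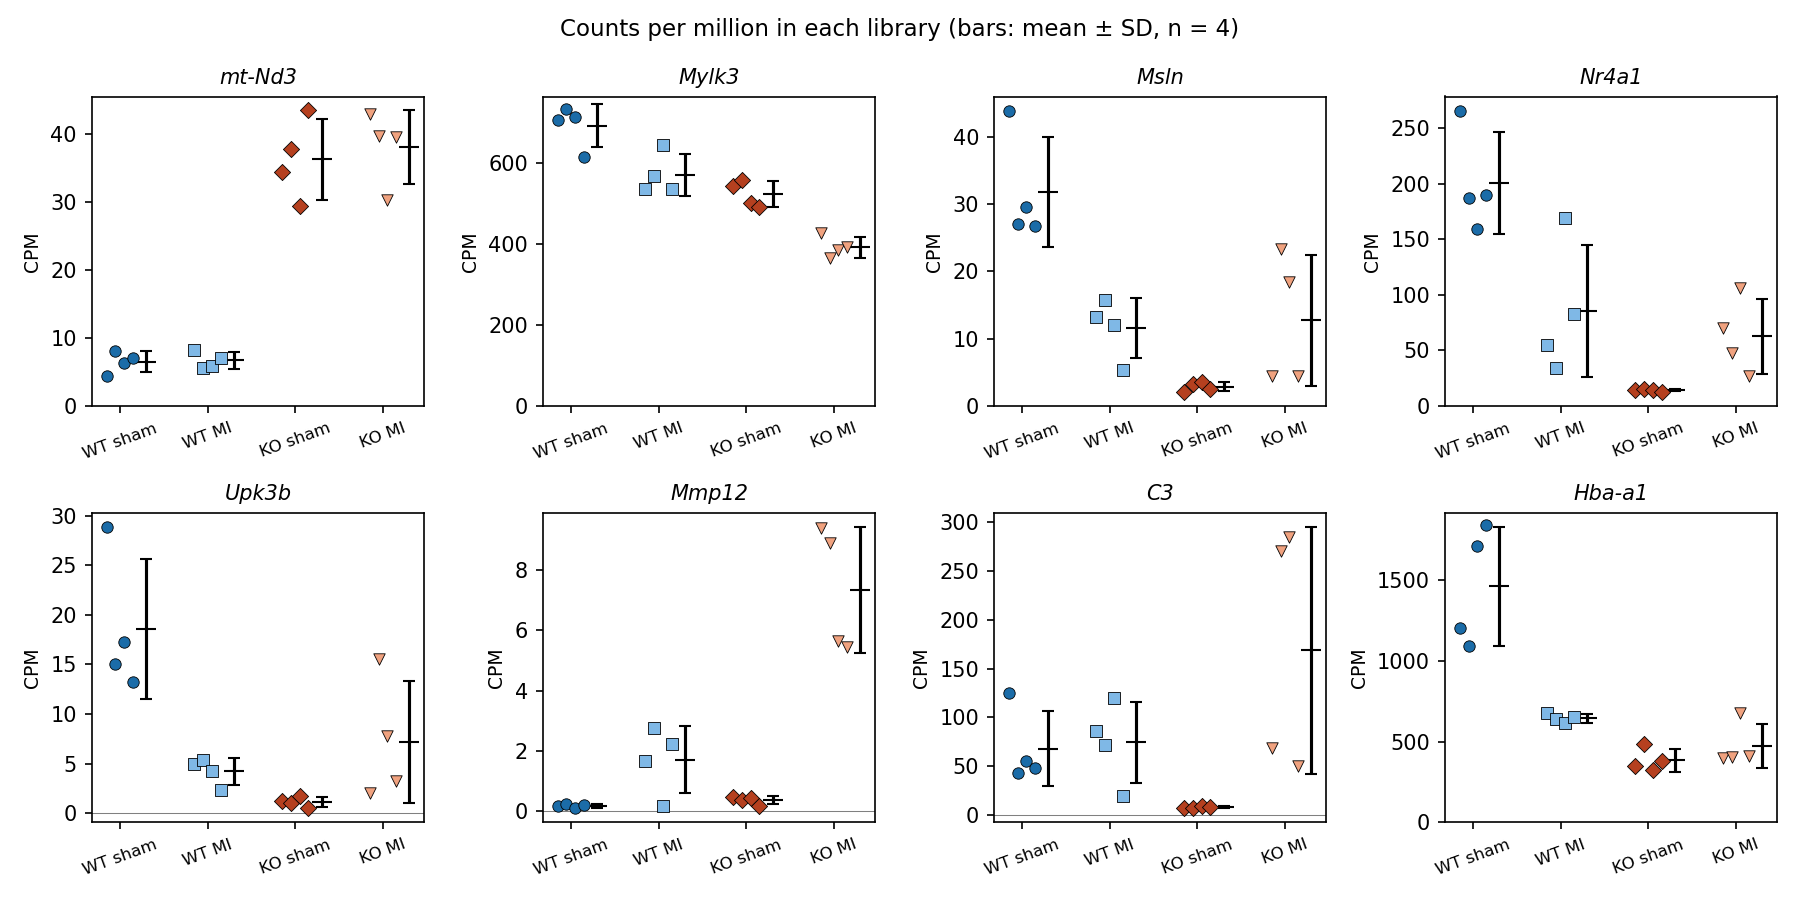
CPM of 8 genes in each library, where points are libraries by group and bars show the mean ± SD (n = 4). For mt-Nd3 the KO libraries sit between 29.4 and 43.6 CPM and the WT libraries between 4.5 and 8.31 CPM.

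The interaction asks whether the response to infarction differed between genotypes. Upk3b rose in knockout relative to wild type by a log2 difference of 4.79 ± 0.80 (SE, n = 4 per group, adjusted p = 0.00633, and 4.08 without KO MI replicate 2), moving from 1.12 to 7.16 CPM in knockout and from 18.6 to 4.19 CPM in wild type. Tnni1 differed by 1.57 ± 0.18 (adjusted p = 0.000122), and Hbb-bt by 1.57 ± 0.21 (adjusted p = 0.000619). In all, the response of 368 genes differed, 221 more positive and 147 more negative in knockout. The number fell to 120 with the atrial index as a covariate (80 and 40). The majority turned without the 3 libraries apart on the fourth principal component (647 more positive and 785 more negative of 1432), and the length and GC correction gave 210 of each. Knockout and wild type differed in 2057 genes after sham and in 2 after infarction, mt-Nd3 and Mylk3. No gene named for the interaction was called between genotypes after infarction. A difference in response can therefore reflect levels already apart in the sham samples.

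Of 14 epicardium and mesothelium genes 11 differed upward, over all genes and adjusted over the list alone (median 2.14, camera adjusted p = 2.78e-14, adjusted p = 0.069 with an estimated correlation), Upk1b by 4.24 and Msln by 3.60. The calls of Msln and of Nr4a1 (3.41 ± 0.68) ended without KO sham replicate 1 or KO sham replicate 4. Of 13 erythroid genes 6 differed upward, and 9 adjusted over the list alone (median 1.11, adjusted p = 0.069 with an estimated correlation), Hba-a1 by 1.48. Of 22 immediate early and handling stress genes 3 differed upward, and 8 adjusted over the list alone (median 0.37, adjusted p = 0.287 with an estimated correlation), among them Nr4a3 by 3.16 and Atf3 by 1.67. Of 30 ribosomal protein genes 1 differed upward, and 28 adjusted over the list alone (median 0.43, adjusted p = 0.287 with an estimated correlation). Of 23 G1/S genes 0 differed over all genes, and 12 upward adjusted over the list alone (median 0.4, adjusted p = 0.41 with an estimated correlation). Of 10 skeletal muscle genes 1 differed upward, and 2 adjusted over the list alone (median 0.34, adjusted p = 0.287 with an estimated correlation), a list call that ended without WT sham replicate 3 (median 0.32). Of 17 unfolded protein response genes 2 differed upward, and 4 adjusted over the list alone (median 0.34, adjusted p = 0.069 with an estimated correlation). Of 18 quiescent fibroblast genes 2 differed downward, and 7 adjusted over the list alone (median -0.29, adjusted p = 0.069 with an estimated correlation). Tnfsf10 differed by -1.97, Galnt15 by -1.91 and the growth factor Csf1 by -0.76. Bcl3, a regulator of NF-kB, differed by -1.18, and beta actin (Actb) by 0.80. The pan-leukocyte list was not called (median -0.01, adjusted p = 0.83), and neither were the monocyte and macrophage, neutrophil and complement lists. Il1b (-0.66 ± 0.96), Nppa (2.36 ± 0.83), Nppb (0.16), Mki67 (0.10 ± 0.18), Ccnb1 (0.27), Aurkb (0.44) and Anln (0.20) did not pass. The number of genes was 178, 194, 218 and 193 without KO sham replicates 1, 2, 3 and 4, and 205 without WT sham replicate 3. It was 231, 817, 234 and 213 without WT MI replicates 1, 2, 3 and 4, 193 without KO MI replicate 2 and 609 without KO MI replicate 4. Of the 46 lists 15 were called, 13 up and 2 down, and none with an estimated correlation.

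**Figure D4:**
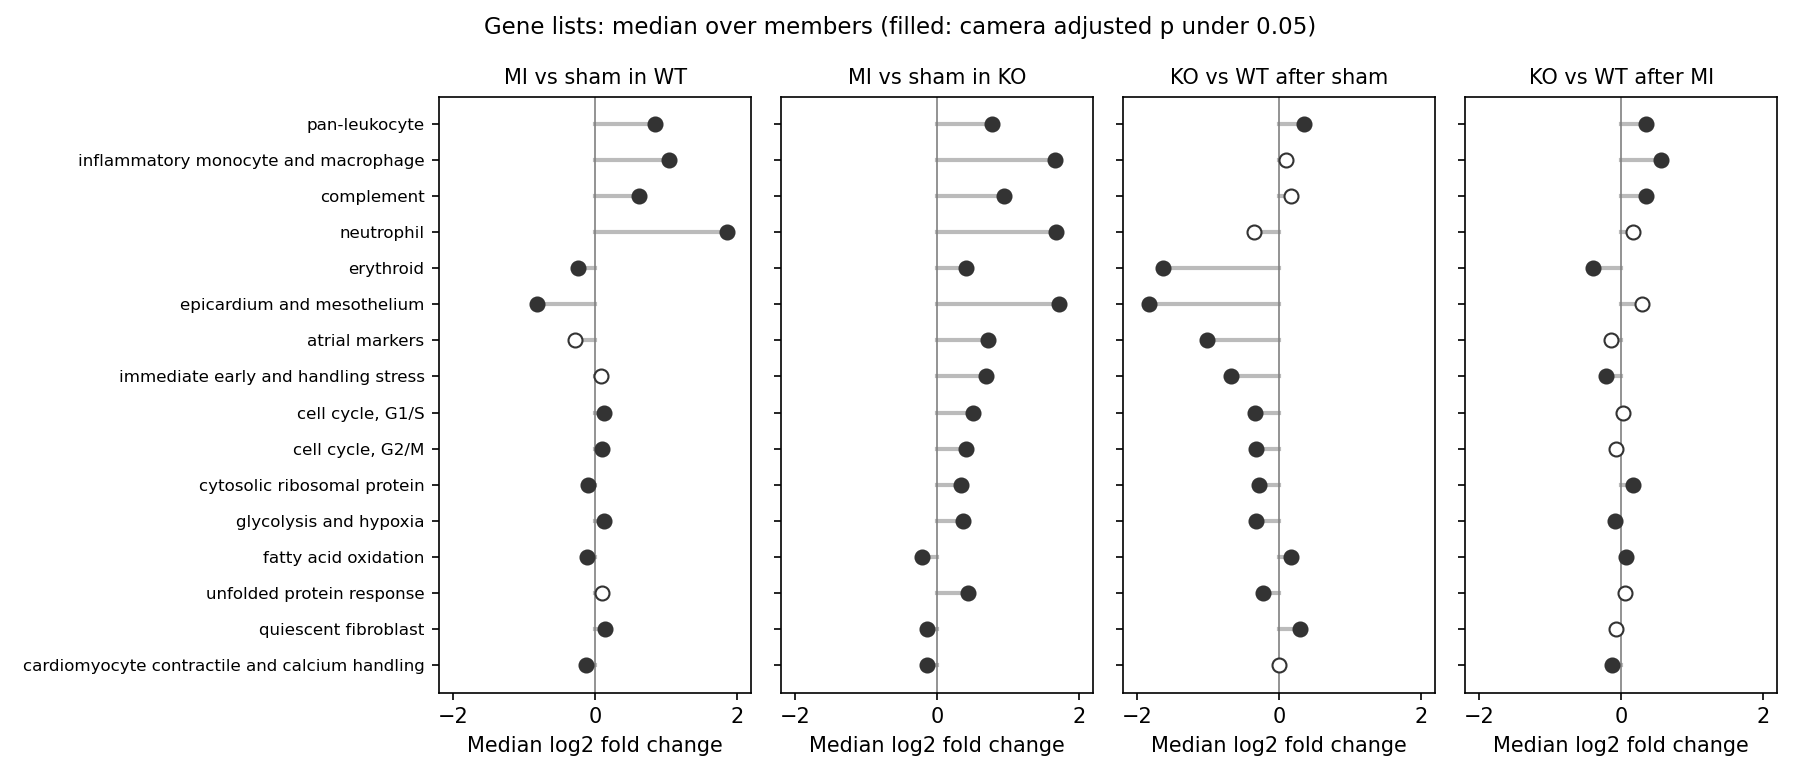
Median log2 fold change of the tested genes of 16 gene lists in 4 comparisons, where each symbol is a list, filled where camera with the preset correlation gave an adjusted p under 0.05. The erythroid median is -1.64 and the epicardium and mesothelium median -1.84 in knockout against wild type after sham.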

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

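The tests of sequencing depth, both tests of mt-Nd3 and the comparison of errors with the atrial covariate were chosen after the results were seen. A sample was singled out where its gap to the nearest of its group exceeded Dixon's 95% critical ratio. This was so in 17 of 179 groups of 4, and chance alone gives about 1 in 20. Among library measures, WT MI replicate 2 held 17223580 gene counts, or 17.2 M (10.9 to 11.8 M in the other 3). Mitochondrially encoded genes took 13.4% in WT sham replicate 2 (9.51 to 9.8 in the others) and 17.4% in KO MI replicate 4 (9.79 to 10.6). Y-linked genes stood at 2.13 CPM in KO sham replicate 2 (211 to 231), and WT sham replicate 2 scored 34.9 on component 2 (17.2 to 18.6). Among genes of KO MI, Arg1 reached 152 CPM in replicate 3 (4.32 to 26.6), Gpnmb 44.9 CPM in replicate 2 (7.48 to 13.8) and Ide 117 CPM in replicate 4 (75.2 to 79.9). Among those of WT MI, Ccl6 was 2.06 CPM (7.41 to 8.31), Dlk1 13.5 CPM (10.9 to 11.3) and Nppa 1800 CPM (1020 to 1100) in replicate 4. Il1b was 10.5 CPM (1.19 to 2.27) and Plin1 1.81 CPM (0 to 0.257) in WT MI replicate 1, and Olfr78 was 1.49 CPM (2.11 to 2.15) in WT MI replicate 2. In WT sham, Dlk1 was 32 CPM (24.8 to 25.6) in replicate 2, Nppb 229 CPM (186 to 189) in replicate 3 and Tmem151a 2.8 CPM (3.93 to 4.15) in replicate 4.

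The response to infarction differed between genotypes for 368 genes and 15 gene lists by the interaction test. This test also takes in differences already present between the sham samples. Of 100 random splits 3 gave as many genes, the real one included, and the highest other gave 955. These splits do not decide whether chance can be excluded: they exchanged surgery labels within each genotype, and the 2 higher ones exchanged all of them in knockout, which leaves the whole response of knockout in the contrast with its sign turned. Another split, which kept 6 labels in knockout and 2 in wild type, gave 336 genes. For infarction against sham, 1 of 35 splits gave as many as the 302 genes in wild type (highest other 12) and 1 of 35 as many as the 2220 in knockout (highest other 0). Only the real split reached these numbers, which argues against a chance split of these samples. The smallest permutation p possible with 35 splits is 0.029. A litter or age difference between the groups, which the labels do not state, could give the same outcome. The same held for knockout against wild type after sham (2057 genes, 1 of 35, highest other 1). It did not hold for the number of genes after infarction, 2 (3 of 35 splits, highest other 5). That number does not bear on mt-Nd3, 1 of the 2, whose adjusted p was 3.14e-08 and which was higher in 8 of 8 KO libraries than in every WT library.

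Knockout and wild type differed in 2057 genes after sham and in 2 after infarction. With every library thinned to the same total 1951 genes differed after sham, which argues against depth as the cause. The atrial index was added as a covariate. With it, the log2 changes of called genes outside the atrial list had a median ratio of 1.13 to those without it (interquartile range 0.87 to 1.34). The index did not overlap between the groups compared (4.71 to 5.89 in KO sham, 6.3 to 8.42 in WT sham). The adjusted values therefore rest on extrapolation from the spread within groups. The changes did not shrink as a set, but this cannot decide whether atrial tissue caused all or part of the difference. With the covariate, the number of genes fell to 928. Among the 1346 genes whose call ended, the median size of the log2 change was 0.48 before and 0.47 with the covariate, while the median SE went from 0.13 to 0.2 and was larger for 1335 of them, so these calls ended mainly with wider errors. A different postnatal maturity of the KO sham hearts stays open: a list of fetal growth genes, written after some of them had been seen to differ, was lower (adjusted p = 1.3e-05; adjusted p = 0.0206 with an estimated correlation), while a list of the maturing heart was not higher (adjusted p = 0.766), and litter, age and an effect of the genotype itself cannot be told apart by the labels.

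The mitochondrial gene mt-Nd3 was higher in 8 of 8 KO libraries than in every WT library, at 37.3 ± 5.37 against 6.65 ± 1.3 CPM. Whether these counts follow the amount of transcript was not tested. More mitochondrial RNA as such is argued against, since the other 12 mitochondrially encoded genes had a median log2 change of 0.09 after sham and 0.08 after infarction. Of these 12, mt-Nd5 was called after sham (0.61 ± 0.14, adjusted p = 0.00559) but not after infarction (-0.25), and mt-Nd4l had the highest change, 1.03 ± 0.40 and 0.76 ± 0.41, without passing in either. A candidate explanation is a sequence difference in the mitochondrial DNA of the colonies that changes which reads align; it stays open, because the reads were not analysed here.

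KO MI replicate 4 stood apart from its group. Its deviation from the others did not follow transcript length (Spearman rho across genes -0.006; -0.366 to 0.394 in the other libraries), which argues against a loss of long transcripts. It fell with GC content (rho -0.486; -0.284 to 0.371 in the other libraries), which is consistent with a GC bias in that library; genes are not independent replicates. No biological explanation was tested.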

How the results depend on the processing

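Leaving out the libraries with almost no Y-linked reads or the 3 libraries apart on component 4, the atrial covariate, thinning and the length and GC correction were chosen after seeing the data. The 302 genes changed by infarction in wild type became 511 with DESeq2, 495 with voom, 185 with both groups fitted alone, 166 without the libraries low in Y-linked reads, 558 without the 3 libraries apart and 454 with the length and GC correction. The 2220 genes in knockout became 4796 with voom, 1291 without the libraries low in Y-linked reads and 3958 without the 3 libraries apart. The 2 genes of knockout against wild type after infarction became 10 with DESeq2, 11 without the 3 libraries apart, and 1 without haemoglobin and mitochondrially encoded genes (which removes mt-Nd3), with both groups fitted alone, without the libraries low in Y-linked reads and with the atrial covariate. The 2057 genes after sham became 3901 with voom, 3211 with both groups fitted alone, 1237 without the libraries low in Y-linked reads and 928 with the atrial covariate. The 368 genes of the interaction became 628 with DESeq2, 1524 with voom, 217 without the libraries low in Y-linked reads, 1432 without the 3 libraries apart and 120 with the atrial covariate. Leaving out single libraries gave 86 to 385, 1230 to 2931, 1 to 4, 1298 to 2077 and 178 to 817 genes in the same order. Leaving out libraries leaves fewer samples, which does not account for the numbers that rose. With the atrial covariate after sham, the median SE of the 1346 genes whose call ended went from 0.13 to 0.2; the other causes were not tested. Lists called numbered 25, 26, 18, 19 and 15 in that order, and 4, 0, 0, 1 and 0 with an estimated correlation. With fry they numbered 9, 25, 0, 18 and 10. Leaving out single libraries gave 21 to 26, 22 to 27, 14 to 23, 17 to 19 and 14 to 19 lists. The correlation of the responses, 0.331, became 0.294 with the strict filter, 0.251 without the 3 libraries apart and 0.26 with the atrial covariate, and 0.25 to 0.376 without single libraries. With a replicate block, although the numbers do not pair the samples, 297, 2413, 3, 2202 and 350 genes and 25, 27, 18, 19 and 16 lists were called, and the correlation was 0.325. Directions reversed for Stard10 after sham with the atrial covariate (log2 0.14), for G1/S genes in wild type without WT MI replicate 2 (median -0.02, up to 0.2 without other libraries), and for G2/M genes there (-0.05, up to 0.21) and without the 3 libraries apart (-0.05). They also reversed for cytokines in knockout with the strict filter (-0.35), and in knockout against wild type after infarction for lung epithelium without the 3 libraries apart (-0.39) and mitochondrially encoded genes without KO MI replicate 4 (-0.17, up to 0.19). Medians turned while the test kept its direction for lung epithelium there without KO MI replicate 4 (-0.04), for cytokines there without WT MI replicate 4 (-0.07) and with the strict filter (-0.04), for mitochondrially encoded genes there without the 3 libraries apart (-0.06) and with the length and GC correction (-0.01), and for atrial genes in knockout with the atrial covariate (-0.08). Of 81 genes named after sham, 39 kept their call with the atrial covariate, 41 lost it and 1 reversed. Of 39 genes named in the interaction, 15 kept their call with this covariate and 24 lost it.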

Other observations

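The test of neighbouring genes was chosen after the result was seen. Metallothionein Mt2 was 3.39 times lower in knockout than in wild type after sham (log2 -1.76 ± 0.26, SE, n = 4; adjusted p = 0.000285) and rose 3.9 times with infarction in knockout; the interaction was 2.07 ± 0.35 (adjusted p = 0.00402). The clock gene Per1 went from 115 ± 14.9 to 52.9 ± 12.5 CPM with infarction in wild type, and was 31.7 ± 2.02 CPM in KO sham and 52.3 ± 23.5 CPM in KO MI. The clock regulator Bhlhe40 rose 2.23 times with infarction in knockout, but of 18 circadian clock genes 5 fell and 2 rose there, and 9 fell and 2 rose adjusted over the list alone (median -0.27, camera adjusted p = 0.0165, adjusted p = 0.157 with an estimated correlation), with Cry2 falling by 0.54 on the log2 scale.

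Among 7 genes that differed between genotypes at an unadjusted p under 0.001 in the same direction after both surgeries, Rab4a and Acta1 on chromosome 8 lay within 1 Mb of each other. Mylk3, also among the 7, is on chromosome 8 too, but was not within 1 Mb of either. Another of the 7, Gabrg3, a subunit of a receptor for the transmitter GABA, is on chromosome 7 within 20 Mb of Chrna7. It stood at 1.51 ± 0.383 CPM in KO sham and 0.233 ± 0.125 CPM in WT sham (SD, n = 4, adjusted p = 0.000464), and at 1.42 ± 0.366 CPM in KO MI and 0.356 ± 0.212 CPM in WT MI (adjusted p = 0.125), with wild type near the detection floor. At least 1 such pair was found in random sets with a permutation p of 0.036, and at a looser cutoff of 0.01 (31 genes, 2 pairs) with a permutation p of 0.18. Donor-strain DNA in neighbouring stretches, around Chrna7 or elsewhere, may contribute. It stays open, since the test was devised after the pair was noticed, the looser cutoff did not pass, and Gabrg3 is a single gene.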
